A study of Mus musculus with 4 samples.

How the data were processed

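RNA of mouse Th2 cells was sequenced in 4 libraries, labelled biological replicates 1 to 4 of 1 group. The assay label reads total RNA, while the linked library protocol names polyadenylated RNA. The labels give 1 donor identifier for all libraries and separate biosamples, and the sex was not collected. The file headers name 48 hours of a Th1 and Th2 time course.

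The deposited tables hold whole counts of read pairs per gene, not normalized, per the file headers from featureCounts 1.4.6-p4 with strand setting 1, pairs with both ends mapped, exons summed by gene, and GENCODE vM13 on mm10. The aligner was STAR by the name of its output, in a version not given in the sources used here. The deposited tables also give exon length per gene (bp). The plan, written before the files were opened, had assumed expected counts and TPM from another quantifier; the tables held counts, so TPM was computed from count and length, and an alternative based on posterior mean TPM could not be run. GENCODE vM21 gave gene names and types only, and 224 of 50600 genes had no match in it. Coordinates are those of the deposited tables.

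Totals were 1785970 to 2271993 counts per library. A gene with 0 counts allows up to 3 counts, or 1.32 to 1.68 CPM. Intervals (95%, Wilson) and floors cover counting error only, since read pairs without molecular identifiers are not independent molecules.

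The gene lists, tests and alternatives, and the rule for named genes, were fixed before the data were examined. The 33 lists cover helper lineages, T cell state, metabolism, stress, cytokines, RNA classes and 10 other cell types. List scores are means over members of log2(TPM + 1), with genes held by both lists left out, and differences and ratios were tested by exact two-sided sign flips over 4 libraries (smallest p 0.125). The named genes are all measured members of the Th2 and Th2 cytokine locus lists, the 3 highest members of each other list with a fixed set of lineage genes, the 12 highest nuclear protein-coding genes outside ribosomal proteins, and, past the replicate-variation threshold, the 15 genes with the largest SD at 5 TPM or more and up to 5 per list. Some of the 3 highest members of a list stood at 0 and are not described. Genes named for an overlap, the genes opposite list members, and the Tsix and Y-linked genes other than Xist, Ddx3y and Eif2s3y were chosen after their values were seen.

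Variation between replicates was tested in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by goodness of fit of an intercept-only negative binomial model with trended dispersion, TMM factors and filterByExpr, and Benjamini-Hochberg adjustment at 0.05. At an unadjusted p under 0.05, 260 of 5064 genes passed. The test was run on simulated data with 1 dispersion for all genes, a biological coefficient of variation of 0.1085. Genes with an expected mean of at least 20 counts were changed, each in 1 library. There it recovered 17% of genes changed 2-fold and 98% of those changed 4-fold, and called 0 of 5295 with no gene changed. The coefficient estimated there was 0.173 with the changed genes and 0.108 with no gene changed, so the recovery rates belong to the higher value. Real genes with and without an exon overlap on the other strand had coefficients of 0.0793 and 0.145, so these rates may not hold for the real calls. Lists with at least 5 tested members were ranked against 10000 random lists in 20 abundance bins, with a prior count of 2. DESeq2 1.42.0 gave size factors and dispersion outliers. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 did the rest.

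An overlap is any exon base shared with a gene on the other strand. Nested pairs needed 90% of the inner gene inside a protein-coding gene's exons and a summed mean of 100 counts. A gene counted as opposite a list member if it was not protein-coding, shared at least 50 bp with it and overlapped no other gene on that strand. Levels of the genes opposite RNA without a poly(A) tail were scaled as CPM of the counts outside CT010467.1 and Gm42418.

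Alternatives were another pseudocount (0.1), FPKM, TMM-normalized CPM, medians over members, other detection and count filters, DESeq2 size factors, a common dispersion, a prior count of 0.5, shares of counts, and leaving out each replicate. Added after the counts were seen were genes with or without an overlap taken alone, the removal of CT010467.1 and Gm42418, the lower gene of a ratio set to at least 3 counts, and leaving out each replicate for the markers of other cell types. Signal tracks were not analysed here, and some values are not reported here.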

Results

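The libraries held RNA of T helper 2 (Th2) cells, the CD4 T cells that make interleukin-4, interleukin-5 and interleukin-13. The cells were primary mouse cells of strain C57BL/6NJ, in 4 biological replicates of 1 group. Totals were 2271993, 2112190, 2204423 and 1785970 counts in replicates 1 to 4, and 14344, 14033, 13557 and 13700 genes had at least 1 count. With 1 group there was no comparison between conditions, so levels were compared within each library, between gene programmes, and between replicates.

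The counts lay mostly in genes whose exons overlap a gene on the other strand. Of 50600 genes, 8189 (16.2%) had such an overlap, and they held 93.4% ± 0.855 of all counts (SD, n = 4). The shares were 92.5% (95% Wilson interval 92.4 to 92.5), 93.1% (93.1 to 93.2), 94.5% (94.5 to 94.5) and 93.3% (93.3 to 93.4) in replicates 1 to 4. All 20 of the genes with the most counts had one. Phykpl, an enzyme gene on chromosome 11 (51584757 to 51604489, mm10), had 62269, 59691, 62490 and 40815 counts, and Hnrnpab, an RNA-binding protein gene that shares 809 bp with it, had 1190, 870, 932 and 561. Gm20721 overlaps Gnas, which encodes a G protein subunit, by 1469 bp: its counts were 39097, 36501, 39620 and 26837, and those of Gnas 146, 110, 107 and 93. In the mitochondrial genome mt-Nd6, the only protein gene on its strand, held 80.9% ± 2.93 (SD, n = 4) of the counts of protein genes. On the other strand mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l had 0 counts in all 4 libraries, and mt-Nd3 had 0, 0, 3 and 0. That share therefore lacks these genes. The rest of that strand ranged from mt-Nd1 (299, 415, 244 and 245) to mt-Nd5 (3494, 3721, 4684 and 3298), so the 0 counts did not hold for the whole strand.

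In 80 pairs a gene lay inside the exons of a protein-coding gene on the other strand. The inner gene was denser in counts in 79 of them, in each of the 4 libraries. The exception was Rps23-ps1, a pseudogene with 3, 0, 2 and 1 counts inside Gm5148, which had 2072, 1694, 1777 and 801. The median density of the outer gene was 0.131%, 0.159%, 0.0972% and 0.142% of the inner one in replicates 1 to 4. The 66 ribosomal protein genes without an overlap, whose mRNAs are among the most abundant in dividing cells, held 0.369% ± 0.0773 of counts (SD, n = 4). A count printed for a gene therefore cannot be read as the level of that gene's own transcript, and every level below is the count or TPM assigned to the named gene in the deposited tables.

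**Figure D1:**
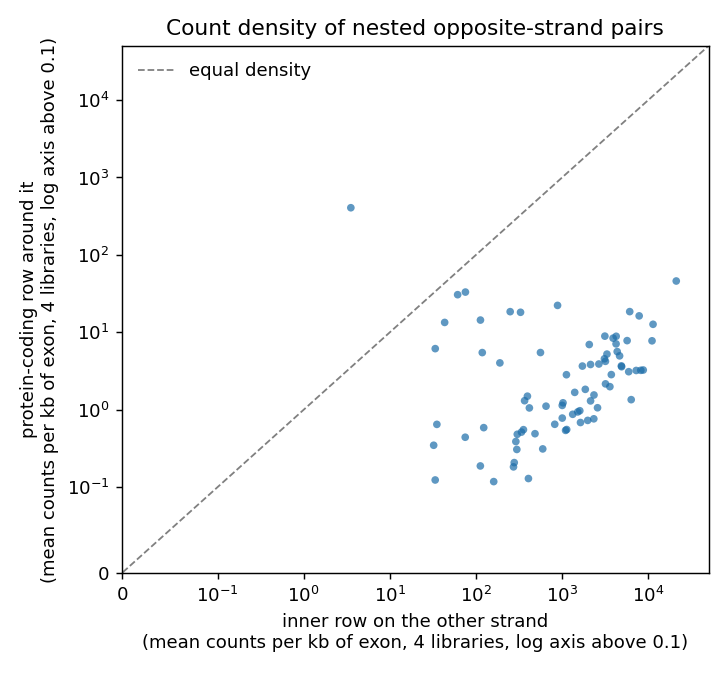
Mean counts per kb of exon over 4 libraries for 80 pairs in which a gene (horizontal axis) lies inside the exons of a protein-coding gene on the other strand (vertical axis); both axes are logarithmic above 0.1. Each point is 1 pair, the dashed line marks equal density, and 79 points lie below it.

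Of the 12 nuclear protein-coding genes with the highest TPM outside ribosomal proteins, each overlapped a gene on the other strand. Gm20721 stood at 17230 TPM ± 869, Gm17606 (opposite Acin1) at 4299 ± 386, Phykpl at 4172 ± 297, Acat3 (opposite the chaperonin gene Tcp1) at 3557 ± 188 and Gm17617 (opposite Zfp346) at 3171 ± 132 (SD, n = 4). Gm26602 (opposite R3hdm4), Mettl23 (opposite the splicing factor gene Srsf2), Tlcd1 (opposite Rpl23a), Fam57b (opposite the aldolase gene Aldoa), Wdr38 (opposite Rpl35), D930007J09Rik (opposite Wrnip1) and 1810049J17Rik (opposite Golph3) ranged from 2183 to 3151 TPM.

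By the counts assigned to their own genes, the Th2 list scored above the Th1 and Th17 lists and below the regulatory T cell (Treg) list in every library. The difference of list scores, each the mean of log2(TPM + 1) over members, was 1.06 ± 0.185 against Th1, 1.23 ± 0.168 against Th17 and -0.57 ± 0.103 against Treg (SD, n = 4; p = 0.125 for each, exact two-sided sign-flip test). With 4 libraries 0.125 is the smallest p this test can reach. With a pseudocount of 0.1 the Th1 and Th17 differences were 1.71 and 2.12. The Treg difference ranged from -1.17 as a median over members to -0.053 with members of at least 1 TPM on average (exact p = 0.75), and was -0.18 with members that have an overlap. Against the follicular helper (Tfh) list it was 0.27 ± 0.125, positive in 4 of 4 libraries (exact p = 0.125), but -0.24 and negative in all 4 when only members without an overlap were used, and -0.13 with TMM-normalized CPM. With only members that have an overlap it was 1.47 ± 0.210. Against the naive and resting list it was 0.16 ± 0.160, positive in 3 of 4 libraries (exact p = 0.25), so about the size of its own spread. It was -0.055 with a pseudocount of 0.1, -0.69 with TMM-normalized CPM and -0.32 as a median over members, and 0.09 without replicate 4, but 0.48 with members of at least 1 TPM on average and 0.46 with members that have an overlap.

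Of the 20 Th2 members, 10 reached 1 TPM in all libraries. The highest was Ptgdr2, a prostaglandin D2 receptor of Th2 cells, at 59.3 TPM ± 8.89, on a gene that shares 1031 bp with Ccdc86 on the other strand. Il4 followed at 18.5 ± 2.46, the transcription factor gene Irf4 at 15.3 ± 2.54, Il13 at 10.8 ± 3.89, Stat6, which carries the interleukin-4 signal, at 10.1 ± 0.490, the chemokine receptor gene Ccr4 at 7.01 ± 2.62 and the lineage factor gene Gata3 at 5.39 ± 1.68 (SD, n = 4). Il4ra stood at 1.95 ± 0.196, Nfil3 at 1.49 ± 0.757, Il17rb at 1.36 ± 0.406 and Ccr8 at 2.15 ± 1.68. Dennd5a, Il10, Areg, Ecm1, Il1rl1 and Maf had means under 1 TPM. Il5, Il9 and Il24 had 0 counts in all 4 libraries, which allows up to 3 counts in each. In the Th2 cytokine locus on chromosome 11, Rad50 stood at 4.84 ± 1.26, Kif3a at 1.18 ± 0.811, Irf1 at 1.04 ± 0.784 and Sept8 at 0.634 ± 0.213.

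Lineage factors and cytokines were also compared as log2 ratios of TPM + 1. Il4 over Ifng, the Th1 cytokine, was 3.97 ± 0.183, Il4 over Il17a 4.27 ± 0.186 and Il13 over Ifng 3.19 ± 0.740, each positive in 4 of 4 libraries (SD, n = 4, exact p = 0.125). Ifng (1, 0, 1 and 0 counts) and Il17a (0 in all) were at or under the floor of 3 counts, so these sizes rest on the pseudocount. With the lower gene set to at least 3 counts they were 2.85 ± 0.264, 2.75 ± 0.268 and 2.06 ± 0.513 (exact p = 0.125 for each), and with a pseudocount of 0.1 they were 6.21, 7.53 and 5.37. Gata3 was above Tbx21 and Bcl6, the factors of Th1 and Tfh cells, by 1.76 ± 0.666 and 2.50 ± 0.249 (exact p = 0.125 for each), with Tbx21 at 1, 5, 2 and 4 counts and Bcl6 at 2, 2, 0 and 0. These sizes rest on the pseudocount too, at 1.57 and 2.23 with the lower gene set to at least 3 counts and 2.62 and 4.92 with a pseudocount of 0.1. Gata3 over Foxp3, the Treg factor, was -4.17 ± 0.420 (exact p = 0.125). The Foxp3 gene (667, 606, 682 and 490 counts) shares 590 bp with Ccdc22, which had 0, 1, 6 and 0 counts. Il5 over Ifng was -0.30 ± 0.347 (exact p = 0.5), with both genes at or under the floor.

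**Figure D2:**
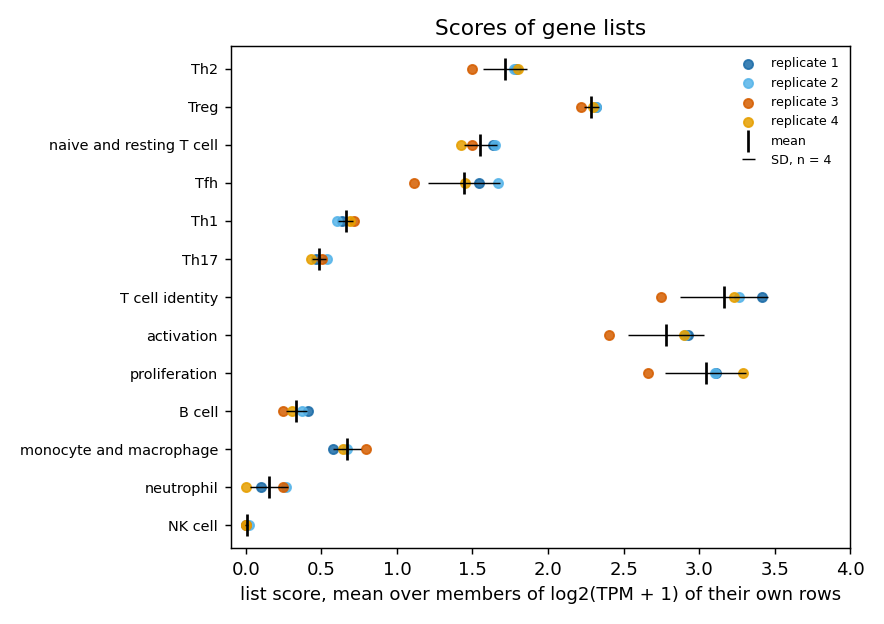
Scores of 13 gene lists in 4 Th2 libraries, each the mean over members of log2(TPM + 1) of the counts assigned to them. Points are replicates, vertical marks the mean and lines the SD (n = 4). Among these 13 lists T cell identity, proliferation and activation score highest, and the NK cell list lies near 0. Housekeeping (4.93) and glycolysis (3.48) scored higher than all 13 and are not shown. The amino acid and ER stress list (3.02), also not shown, scored above activation.

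Where the gene opposite a Th2 or T cell gene was not protein-coding and overlapped no other gene on that strand, it mostly held more counts in every library: 4 of 4 pairs of the Th2 list, 2 of 3 of the T cell identity list, 1 of 1 of the activation list, 3 of 4 of the naive and resting list and 2 of 4 of the cytokine list. The same held in 2 of 2 pairs for cholesterol synthesis, 4 of 5 for hypoxia and 2 of 3 for glycolysis. It was thus not particular to T cell genes. For other helper lineages it held in 0 of 2 pairs for Th1, 1 of 2 for Th17 and 1 of 2 for Treg. Gm13256, antisense to Gata3 on chromosome 2 with 155 bp shared, had 2300, 2218, 2625 and 2048 counts, against 44, 35, 21 and 20 for Gata3. Gm12214 lies in Il5 (417 bp) and had 72, 95, 48 and 46 counts where Il5 had 0, and Gm15655, opposite Maf, had 6, 5, 6 and 3 where Maf had 0, 0, 1 and 0. Gm44876, opposite the interleukin-4 receptor gene Il4ra, had 631, 711, 764 and 511, and Gm12223, opposite the cytokine gene Csf2, had 2423, 2309, 1981 and 1445. Opposite T cell genes, Gm48719 (Cd3e) had 2351, 2067, 2361 and 1692, and Gm16008 (Tnfrsf18, a receptor of activated and regulatory T cells) 6486, 5955, 6850 and 4975. Opposite naive-state genes, Bach2os had 1593, 1825, 1879 and 1433 and Gm43352 (Lef1) 1122, 1066, 1057 and 794. The reverse held for Gm15417 (6, 11, 12 and 6) and Zbtb7b, a factor of CD4 T cells (30, 37, 37 and 41), for Gm6934 (68, 73, 69 and 46) and Satb1 (193, 128, 125 and 126), for 2310044K18Rik (11, 14, 13 and 10) and Il16 (21, 16, 14 and 14), and for Gm12534 (12, 10, 9 and 13) and Il21 (44, 32, 30 and 23). Pairs of protein-coding genes are outside these numbers. Ptgdr2 (249, 263, 216 and 147) had more counts than Ccdc86 opposite it (24, 7, 5 and 8). Cd247 (1360, 1364, 1278 and 972) had more than Pou2f1 (330, 267, 331 and 180). Which gene's transcripts gave the counts of such a pair was not tested, so the higher gene need not be the more expressed.

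Opposite genes of other helper lineages, Gm33460, opposite the Th1 factor gene Eomes, had 3, 2, 1 and 0 counts, and Gm20743, opposite Xcl1, had 1, 2, 0 and 0. Gm15511 (opposite the Th17 factor gene Rora) had 19, 12, 6 and 8, and Gm29114 (opposite the Treg factor gene Ikzf2) 6, 9, 9 and 9. Eomes itself had 2, 3, 5 and 2 counts, Xcl1 0 in all, Rora 2, 1, 4 and 2, and Ikzf2 1, 1, 0 and 0. Gm36995, opposite Foxp3, had 0 in all, and the protein-coding gene Serbp1, opposite the Th1 gene Il12rb2, had 575, 381, 369 and 327. In total 50 genes lay opposite list members and 32 of them had more than 3 counts in every library. Of 7 opposite members of the lists of other cell types, 1 did: Gm43434, opposite Trdc, with 7, 10, 12 and 6. These pairs were chosen after the counts had been seen, and different lengths and overlaps keep their counts from being ranked against each other.

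**Figure D3:**
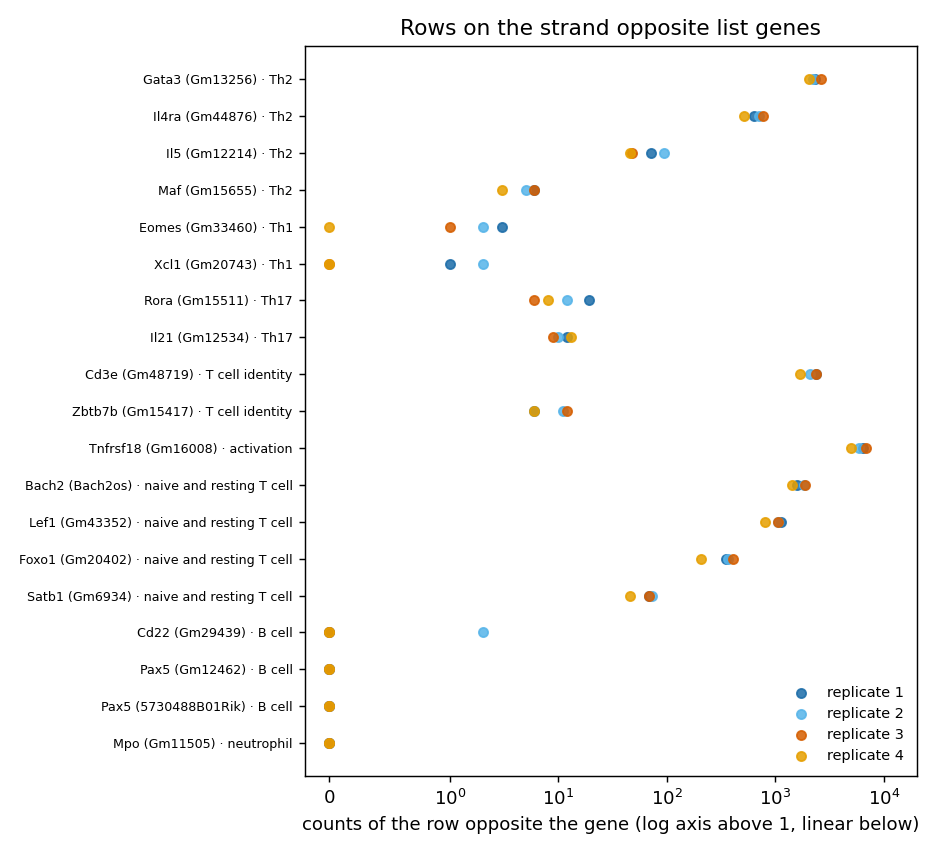
Counts per replicate of genes lying opposite members of 8 gene lists (list gene first, opposite gene in parentheses, then the list). The axis is logarithmic above 1 and linear below; the genes opposite Gata3 and Cd3e lie between 1692 and 2625 counts in the 4 libraries, and those opposite Pax5 and Mpo at 0.

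By the counts assigned to them, T cell, activation and growth genes were detected broadly. Of 19 T cell identity genes, 17 reached 1 TPM in all libraries: Cd247 (T cell receptor zeta chain, sharing 3007 bp with Pou2f1) at 168 ± 8.39, Cd6 at 30.0 ± 4.65, Trbc2 at 15.5 ± 9.57 and Cd4 at 11.5 ± 2.54 TPM (SD, n = 4). Of 21 activation genes 16 did, with Il2 at 75.5 ± 22.6, Batf at 27.8 ± 2.32 and the amino acid transporter gene Slc3a2 at 23.5 ± 1.78. Of 24 proliferation genes 21 did; Ccna2 (197 ± 10.8) and Ccne2 (87.4 ± 10.5), both cyclins, and Mcm7 (20.4 ± 2.57) each overlapped a gene on the other strand. Of 17 glycolysis genes 15 did, with Pfkp at 79.6 ± 6.41, Ldha at 57.0 ± 16.4 and Tpi1 at 41.0 ± 10.97. Of 10 housekeeping genes 9 did, with Eef1a1 at 268 ± 69.5, Tbp at 126 ± 9.36 and Rplp0 at 109 ± 25.7. Pfkp shares 372 bp with Pitrm1 on the other strand, and Tbp shares 2582 bp with Pdcd2.

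Stress, sterol and cytokine genes were detected in part. Of those named here, Ddit3, Hsp90b1, Junb, Cyp51, Fdft1, Car9, Ankrd37, Usp18, Irf7 and Lamp1 each overlapped a gene on the other strand. Of 15 genes of amino acid and ER stress 10 reached 1 TPM in all libraries (Ddit3 172 ± 8.74, Hsp90b1 54.3 ± 9.16, Atf4 42.9 ± 11.3), of 16 for cholesterol synthesis 9 did (Cyp51 7.76 ± 2.53, Fdft1 6.53 ± 1.36, Mvd 6.39 ± 3.08), and of 14 immediate early and heat shock genes 6 did (Junb 116 ± 10.8, Ier2 21.5 ± 3.54, Hsph1 5.00 ± 1.51). Of 12 hypoxia genes 4 did (Car9 5.27 ± 1.11, Ankrd37 3.21 ± 1.04, Ddit4 3.00 ± 1.64), and of 24 cytokine genes 13 did, with Il3 at 12.8 ± 3.49. Of 8 inhibitory receptor genes 3 did: Tigit (6.05 ± 1.79), Ctla4 (5.63 ± 1.92) and Pdcd1 (4.28 ± 1.25). Of 18 interferon response genes 2 did, Usp18 (3.87 ± 0.904) and Irf7 (3.86 ± 0.801), while Bst2 averaged 2.35 ± 2.09. Of 12 cytotoxic granule genes 1 did, the lysosomal gene Lamp1 (5.67 ± 0.744), with Gzmf at 0.922 ± 1.39 and Nkg7 at 0.186 ± 0.372. Of 10 chemokine genes 1 did, Ccl3 (2.57 ± 0.679), with Ccl4 at 0.784 ± 1.02 and Ccl17 at 0.664 ± 0.767. Ccl3 had only 4, 2, 3 and 2 counts. A gene can thus reach 1 TPM in all libraries at or near the floor of 3 counts.

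The Th1 and Th17 lists held few genes detected by their assigned counts. Of 16 Th1 members 2 reached 1 TPM in all libraries; Il12rb2 (10.99 ± 1.11) shares 1519 bp with Serbp1, Cxcr6 stood at 2.30 ± 0.599, Runx3 at 1.79 ± 0.955 and Tbx21 at 0.913 ± 0.597. Of 13 Th17 members 2 did, Il21 (4.39 ± 0.781) and Tmem176a (2.01 ± 0.463), with Tmem176b at 0.633 ± 0.478. Of 12 Treg members 8 did, with Foxp3 at 111 ± 3.96, Nrp1 at 18.9 ± 1.19 and Izumo1r at 6.40 ± 1.82. Foxp3 shares 590 bp with Ccdc22 on the other strand, so its counts need not come from its own transcript. Of 10 Tfh members 4 did (Btla 15.7 ± 3.21, Cd200 10.01 ± 3.64), with Cxcr5 at 0.969 ± 0.466, and of 12 naive and resting members 7 did (Lef1 11.5 ± 0.936, Tcf7 10.8 ± 2.87, Ccr7 5.47 ± 2.19).

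Counts assigned to markers of other cell types were mostly near the floor. This sets no limit on their own transcripts, since Cd3e, a T cell gene, had only 18, 20, 6 and 9 counts. Of 87 measured members of 10 lists, 9 reached 1 TPM in all libraries and 14 exceeded 3 counts in some library. Csf1r (196 ± 5.16), the macrophage growth factor receptor gene, shares 871 bp with Hmgxb3, and Alas2 (9.73 ± 0.774), a heme synthesis gene, shares 311 bp with Apex2. The 7 without an overlap were Cd74 (5.22 ± 2.13), H2-Ab1 (4.54 ± 1.33) and H2-Eb1 (3.62 ± 2.19) of class II presentation, the B cell genes Cd79a (4.09 ± 1.84) and Ighm (2.25 ± 0.951), the endothelial gene Pecam1 (2.96 ± 1.05) and the macrophage gene Cd68 (1.71 ± 0.710; all TPM, SD, n = 4). Of the CD8 T cell genes, Cd8b1 stood at 1.46 ± 0.492 and Cd8a had 1, 0, 0 and 0 counts. Camp (1.81 ± 1.66), a neutrophil gene, Tyrobp (1.28 ± 1.93) and Hdc (0.801 ± 0.286), a mast cell and basophil gene, did not reach 1 TPM in all. The NK cell list had 1 count in 1 library (Klrk1), and the gamma delta list no member above 3 counts (Sox13 3, 0, 0 and 0).

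RNA classes were given as shares of TPM. Mitochondrial genes held 6.24% ± 0.490, ribosomal protein genes 0.544% ± 0.109, replication-dependent histone genes, whose mRNAs end without a poly(A) tail, 0.00165% ± 0.000543, and immunoglobulin genes 0.00126% ± 0.000340 (SD, n = 4). Ribosomal RNA genes held 2.80%, 2.00%, 3.09% and 10.3% in replicates 1 to 4, nearly all in CT010467.1 (chromosome 17, 39846353 to 39848827), which had 102954, 68555, 110661 and 283933 counts. Malat1, a nuclear RNA, had 30, 20, 9 and 16 counts, and Gm37376 opposite it had 683, 730, 600 and 618.

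The 4 libraries had like profiles. Between pairs of libraries, Pearson's r of log2(TPM + 1) was 0.946 to 0.957 across 9091 genes, which are not independent replicates. In all 4 libraries 6730 genes reached 1 TPM (4742 protein-coding), of which 3752 overlapped a gene on the other strand and 2978 did not. Read counts of any pair differed by 3.30 to 39.9 chi-square units per degree of freedom, and by 2.33 to 4.09 without CT010467.1 and Gm42418.

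Of 5064 genes tested with edgeR, 23 varied between replicates by more than genes of like abundance (adjusted p under 0.05), with a biological coefficient of variation of 0.108. In replicate 4 alone, counts were highest for CT010467.1 and its partner Gm42418 (189, 80, 88 and 592), Ccdc107, which overlaps the RNase MRP gene Rmrp (47, 55, 58 and 309; edgeR adjusted p = 2.01e-29), and Gm20628, which overlaps the histone gene Hist2h3b (17, 15, 21 and 72; edgeR adjusted p = 1.73e-06). Ddx1, an RNA helicase gene, had 35, 226, 195 and 20 counts (edgeR adjusted p = 2.66e-20). The mitochondrial gene mt-Nd4 had 1185, 1077, 2519 and 1758, and mt-Co1 687, 788, 355 and 429. The actin regulator gene Actr3 (64, 38, 13 and 54), the chromatin remodeller gene Hells (77, 70, 19 and 49), the cytokine signalling kinase gene Jak2 (231, 237, 85 and 145) and the translation genes Eef2 (580, 448, 305 and 476), Tpt1 (281, 200, 122 and 217) and Eef1a1 (1195, 869, 661 and 928) were lowest in replicate 3. Gm23935 (124, 50, 73 and 134), Gm26917 (29, 46, 92 and 52), C230062I16Rik (112, 127, 140 and 197) and Lars2 (27, 17, 12 and 44) completed the named set. Of the 23 genes, 14 had no overlap, among them Actr3, Hells, Jak2, Eef2, Tpt1 and Eef1a1, and in a fit of genes without an overlap alone 3 of the 14 were past the threshold (Ddx1, Gm26917 and mt-Nd4). Without replicate 4 the test called 7 genes, and without replicate 3 it called 12. The filter asked for enough counts in all 4 libraries, so genes near 0 in any library were not tested. Fgfbp3 (4, 92, 1 and 4 counts) was called only without the filter.

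Of 11 gene lists with enough tested members, 5 had a median SD at or above the 95th percentile of random lists of like abundance: proliferation, housekeeping, amino acid and ER stress, activation and glycolysis. The Th2 list lay at percentile 12.1, Treg at 17.6, cytokine at 18.3, cholesterol synthesis at 57.3, naive and resting at 58.5 and T cell identity at 94.4. With only genes that lack an overlap, 0 of 8 lists reached the 95th percentile. Without replicate 3 the number of lists that reached it was 2. The 503 genes without an overlap and with at least 50 counts on average had a median level of 1.11, 0.968, 0.833 and 1.11 relative to their own mean in replicates 1 to 4, against 0.993, 1.00, 1.01 and 0.999 for 2248 genes with one, and 308 of the 503 (61.2%) were lowest in replicate 3.

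Tsix and Xist differed between the libraries, and the few Y-linked counts lay in replicates 3 and 4. Tsix, antisense to Xist on the X chromosome (103431517 to 103484957), had 2752, 3012, 8 and 3 counts, and Xist, the RNA that silences an X chromosome in female cells, had 56, 50, 3 and 4. The Y-linked genes Ddx3y (0, 0, 6 and 4), Eif2s3y (0, 0, 5 and 1), Kdm5d (0, 0, 5 and 3) and Uty (0, 0, 1 and 0) together had 0, 0, 17 and 8. The filter on low counts asks for enough counts in all 4 libraries, and it kept these genes out of the edgeR test. Without the filter Tsix, Xist and Gm27520, which also lies opposite Xist, were past the threshold of the test. None of the 4 Y-linked genes was.

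**Figure D4:**
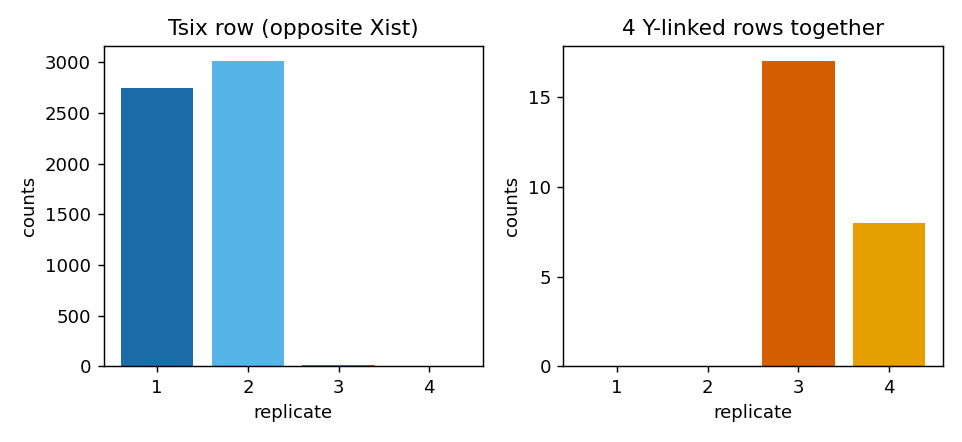
Counts per replicate of Tsix, which lies opposite Xist (left), and of 4 Y-linked genes together (right). Bars are single libraries without error; Tsix stands at 2752 and 3012 counts in replicates 1 and 2 and at 8 and 3 in replicates 3 and 4.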

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

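All tests of explanations below, and the bounds they were held to, were chosen after the results were seen. Of 238 values looked at across the 4 libraries, 31 had 1 library far from the others, against 11.9 expected, since chance alone gives about 1 in 20. Of these, 12 had the other 3 libraries equal, as low counts do, and 3, 4, 11 and 13 lay in replicates 1 to 4; several repeat the same counts.

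In replicate 4 the share of TPM in ribosomal RNA genes was highest at 10.3%, with CT010467.1 at 102198 TPM and 189106 CPM (scaled outside CT010467.1 and Gm42418). Highest there too were Gm42418 at 287 TPM and Ccdc107, the gene opposite Rmrp, at 177 TPM and 206 CPM. The same held for Gm20628 at 19.9 TPM and the genes opposite histone genes at 225 CPM. Also in replicate 4, 1810049J17Rik was lowest at 1683 TPM, 4930483K19Rik, opposite the sterol gene Lss, was highest at 556 CPM, and Areg stood at 1.46 TPM and Trdv5 at 1.33 CPM with 0 elsewhere. Replicate 3 was lowest for the Th2 list minus the Th1 list (0.78) and for the scores of the Th2 (1.496), activation (2.41), amino acid and ER stress (2.53) and interferon response (0.34) lists, and highest for the sex-linked list (0.45), Fam57b (2622 TPM) and Gm26762, opposite Gpi1 (6409 CPM). It alone had counts for Il1rl1 (0.0986 TPM), Maf (0.0825 TPM) and Nkg7 (0.744 TPM). Replicate 2 alone had counts for the NK cell list (score 0.0193), Klrk1 (0.0980 TPM), Mpo (0.411 TPM) and Gm29439, opposite Cd22 (0.979 CPM), and replicate 1 alone for Cd8a (0.182 TPM), Cpa3 (0.436 TPM) and Sox13 (0.460 TPM).

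Counts were concentrated in genes that overlap a gene on the other strand. A library without strand would give both genes of a nested pair like densities, yet the inner gene was denser in 79 of 80 pairs. Antisense transcription counted on the right strand would leave ribosomal protein mRNAs abundant, yet those without an overlap held 0.369% of counts, where at least 1% was asked for. A strand setting opposite to that of the libraries remains a candidate explanation, under which the median density of the mRNA gene, 0.132% of the gene inside it, would be what is left of its own strand. It was found and tested on the same counts, and a recount of the reads with the other setting would settle it.

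Replicate 4 had more counts in CT010467.1, a gene annotated as ribosomal RNA, and in genes opposite Rmrp and histone genes. More cells in S phase would not raise the gene opposite Rmrp, which stood 8.09 times above the mean of the other libraries, but for the histone genes it stays open, since the only test was the gene opposite Plk1 (0.980), which marks later phases. Genomic DNA was first tested on 34546 genes without an overlap and with under 1 count on average, and that test came out in its favour, at 1.34 times the other libraries against at most 1.05 elsewhere; a test by strand, added after that outcome, argued against it for the pattern, since DNA gives both strands alike and Gm42418 had 0.209% of the counts of CT010467.1, and Rmrp with the histone genes 0.155% of those opposite them. A little DNA in replicate 4 beside the pattern is thus not excluded. Weaker removal of RNA without a poly(A) tail may account for it: genes opposite histone genes stood at 2.10, or 1.79 without Gm20628, which had drawn attention to them, and those opposite polyadenylated histone variants at 0.961.

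Tsix and the Y-linked genes had opposite levels in the libraries. If each library mixed both sexes, Tsix in replicate 3 would not fall to 0.259% of the library with the most. Loss of Xist from XX cells in culture would leave no Y-linked counts, yet replicate 4 had 8 and replicate 3 had 17. Animals of different sex could give the pattern, since each of the 4 libraries had either Tsix above 100 counts or Y-linked counts and not both. Under the candidate strand setting above, counts of Tsix in the 1943 bp it shares with Xist would come from Xist. Which transcript gave them was not tested. Xist itself was also higher in replicates 1 and 2 (56, 50, 3 and 4 counts). The labels give no sex, so animals of different sex are a hypothesis from the same counts.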

How the results depend on the processing

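Chosen after the counts were seen were the settings restricted to genes with or without an overlap, those without CT010467.1 and Gm42418, the lower gene of a ratio set to at least 3 counts, and leaving out each replicate for the markers of other cell types; the others were planned. The Th2 list stayed above the Th1 and Th17 lists and below the Treg list under every setting run, and the ratios kept their sign, but the difference from the Treg list shrank to -0.053 with members of at least 1 TPM on average. The Th2 list minus the Tfh list became -0.13 with TMM-normalized CPM and -0.24 with members that lack an overlap. The Th2 list minus the naive and resting list became -0.055 with a pseudocount of 0.1, -0.69 with TMM-normalized CPM and -0.32 as a median over members. The cause of these changes was not tested. With 4 libraries no list difference or ratio could pass 0.05, so the p-values say nothing about stability.

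Detected genes numbered 3648 at 5 TPM, 5103 with at least 10 counts and 2978 without an overlap. The lowest r between libraries was 0.869 with a pseudocount of 0.1, 0.956 without a filter and 0.970 with TMM-normalized CPM. Genes varying between replicates numbered 15 without a filter (9 shared with the 23), 32 with a common dispersion (17 shared), 21 among genes with an overlap (9 shared) and 3 among genes that lack an overlap, where 11 of 14 calls were lost; the cause was not tested. The coefficient of variation was 0.137 without a filter, 0.0793 with an overlap and 0.145 without one. Of the gene lists, 0 remained at or above the percentile among genes that lack an overlap. As shares of counts, mitochondrial genes held 1.93%, histone genes 0.000672% and immunoglobulin genes 0.000532%.

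Leaving out each replicate gave ranges of 7 to 20 varying genes, 0.0915 to 0.128 for the coefficient of variation, 2 to 7 lists and 0.946 to 0.953 for the lowest r. The alternative with posterior mean TPM was not run, since the tables hold counts. A count of 0 allows up to 3 counts assigned to that gene and sets no limit on its own transcript.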
